A study of Glycine max with 12 samples.

How the data were processed

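Gene expression was measured by RNA sequencing in 12 libraries of soybean leaf, 6 from weedy and 6 from control plots. Per the labels' protocols, RNA was extracted with Trizol and a column kit, libraries were made from 4000 ng of RNA with the Illumina TruSeq RNA kit, and they were sequenced in paired ends on an Illumina HiSeq2000. The strand is not stated, so reads of overlapping genes and antisense partners cannot be separated.

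The authors deposited 1 table of the whole series. Per the file headers, its library columns are log2 FPKM values made by the authors with the Tuxedo programs and annotated with Phytozome gene models, and the submitters' processing notes name TopHat, Cufflinks and Cuffdiff, each as version 1.0. The genome build is not given in the sources used here. Sorted values were identical in all 12 library columns, ran from 0.00 to 13.50 with a median of 3.22, and held 10 zeros each. The authors therefore deposited log2 values that had been brought to a common distribution, by a step not given in the sources used here, and neither is it stated whether a number was added before the log. A deposited log2 value near 0 can thus be a low or a floored estimate. The deposited table also holds, per the file headers, 4 log2 ratio columns of weedy to control per season, which were recomputed from the library columns with a largest difference of 0.000000, p-value and q-value columns that the authors obtained from Cuffdiff for 2010 and 2011, and a text label of genes that moved alike in several seasons. Read counts and totals are not part of that table, so depth is unknown, and no interval or floor that needs it is given. Quantile scaling hides a change shared by most genes, since every library is forced to 1 distribution.

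Samples were grouped by the treatment and replicate in their titles. The labels give 1 sampling date per season, June 23 in 2008, June 25 in 2009, June 22 in 2010 and June 29 in 2011, with precipitation of 12.4, 9.9, 19.4 and 24.2 cm and temperatures of 23.9, 27.2, 25.6 and 26.1 °C. Replicate 1 carries a row spacing of 76 cm and replicate 2 of 18 cm, which was read from a label field named after read files and is an inference. The label of the 2009 control plot dates its herbicide to June 26. The label of weedy replicate 2 of 2011 calls its second read file corrupt, and how that library was then processed is not given in the sources used here.

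Of 30498 table entries, 39 entries shared 19 gene identifiers and were left out, because the table does not say which entry is which gene. Of the 30459 genes left, those with a log2 value of at least 1 in at least 3 libraries were tested, which removed 3 and left 30456. The test plan, made before the data were examined along with the groups, the 19 gene lists, the rule for named genes and a list of other settings to try, assumed linear values and log2 of the value plus 1. The deposited log2 values were used as they stand instead. Differences were fitted with limma 3.58.1 in R 4.3.3 (eBayes with trend and robust options, statmod 1.5.0) and p-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05 and two-sided tests. Weedy minus control used all 12 libraries with the season as a covariate. The effect within 2010 and 2011, its difference between them, row spacing, and the interaction of weeds with spacing used the 8 libraries of those seasons, and the test of seasons was an F test over all 12.

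Gene lists were joined through the Arabidopsis locus that the deposited table pairs with 29874 entries, and through keywords in its descriptions. No gene identifier matched the reference gene table supplied (0 matched), so names are those of the deposited table. Of the 19 lists 18 had at least 5 members and were tested with camera (preset correlation of 0.01, and an estimated correlation) and with fry, both in limma. They cover light and shade signalling, auxin, gibberellin, ethylene, jasmonate, salicylate and defence, abscisate and drought, clock and flowering, photosynthesis, phenylpropanoids and flavonoids, cell wall extension, the cell cycle, nitrogen and sugar starvation, iron, heat shock, glutathione and detoxification, leaf age and meristem, and vascular wall. The last, of root nodule and seed proteins, had 0 members in the table and says nothing of other tissues. Many lists rest largely on keywords, such as a description containing heat shock. Fry's p tests whether a list moves on balance in 1 direction and does not compare it with other genes. The adjustment of members over a list alone was made within each list and not across the 18 lists.

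The rule for named genes took, for weedy against control, the 12 largest rises and 12 largest falls among genes past the threshold that moved alike in all 6 pairs, and the 2 members of smallest p in each list. For the other comparisons it took the 4 largest rises and 4 largest falls. Where fewer passed, it took those and then the 3 of smallest p on each side, given as values that did not pass. Genes named outside the rule are said to be chosen after their values were seen.

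Weedy and control libraries share season and replicate numbers. The labels give both members of a pair 1 sampling date, and the correlations of their deviations from the group means were 0.90, 0.59, 0.71, 0.57, 0.63 and 0.49 for the 6 pairs, all above 0.1, the bound set for treating the numbers as pairs. These deviations keep the season, and 2 control libraries, replicate 2 of 2010 and replicate 1 of 2011, correlated better with another weedy library (0.68 and 0.71) than with their own partner. With the season removed, the difference between the plots of a group in 2010 correlated at -0.05 between the groups, and in 2011 at 0.05, across genes, which are not independent. The values thus show a shared season and no pairing by number within it, and in 2010 and 2011 a pair is 2 plots of 1 season, number and spacing. This check was added after the data were seen. The replicate block was run as an alternative and gave 0 genes in weedy against control.

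The alternatives tried were the fit without the season, the replicate block, quantile normalization, no filter, a pseudocount of 0.1, an estimated correlation, and leaving out each library and each season. Added after the data were seen were reading the values as log2 FPKM and testing log2 of FPKM plus 1, a minimum mean log2 value of 2, eBayes without trend or robust options, the lists in further comparisons and with libraries left out, and a leaf stage covariate. Tests for counts were not run, since there are no counts.

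The fitting code was tested on simulated data with the real genes' levels and spread, in which 200 of 30456 genes were changed by a known size. For weedy against control it recovered 43.5% at a log2 change of 0.5, 91% at 1 and 100% at 2, with 1, 6 and 6 false calls. Within 2011 it recovered 0%, 38% and 93%, and for row spacing 0%, 69.5% and 95.5%. Of 20 simulated lists of 50 genes the 1 shifted by 0.3 was called by camera and by fry, and 0 of the others were. Simulated genes varied independently of each other, unlike real ones. The changed genes were drawn at random, and 200 true changes at once ease the adjusted threshold. In the real data HSP81-1 Glyma16g29750 did not pass over all genes at a log2 difference of -1.77 (limma, adjusted p = 0.101). A count of 0 genes therefore does not exclude changes of 1 or more. Data were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.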

Results

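RNA from young soybean leaves was sequenced in 12 libraries over 4 field seasons, 2008 to 2011, to compare plants that grew among weeds with plants kept free of weeds by herbicide. Each library held the newly opened trifoliate leaf, under 2 cm long, of at least 8 plants of the cultivar AG1631 from 1 plot near Brookings. There were 6 weedy and 6 control libraries, 1 of each in 2008 and in 2009 and 2 of each in 2010 and in 2011. The labels call them biological replicates, and each replicate is a plot. The weeds differed between seasons: velvetleaf and buckwheat at about 300 plants per square metre in 2008 and at about 48 in 2009, flax at about 600 in 2010, and velvetleaf and sunflower at about 160 in 2011. Control plots received S-metolachlor in 2008, sethoxydim in 2009, glyphosate in 2010 and a mixture of herbicides in 2011, so herbicide and weeds differ together between the groups, although the label dates the 2009 spraying to June 26, after the sampling of June 25. The deposited values are log2 expression levels of 30498 table entries, scaled so that all 12 libraries share 1 set of values from 0.00 to 13.50. They hold no read counts, so the sequencing depth behind each value is unknown. Gene names are those of the Arabidopsis match given in the deposited table, and soybean often carries several near-identical copies under 1 name, between which reads may have been divided.

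Season set the libraries apart more than weeds did. The first principal component held 50.8% of the variance and separated the control and weedy libraries of 2008, at -97.8 and -110, from the others, which lay between -37.1 and 71.1. The second component held 20.3% and placed the 4 libraries of 2011 between 42.4 and 51.7, against -41.2 to -12.3 for the rest. In 2010 both weedy libraries lay above both control libraries on the first component, and in 2011 both lay below them.

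**Figure D1:**
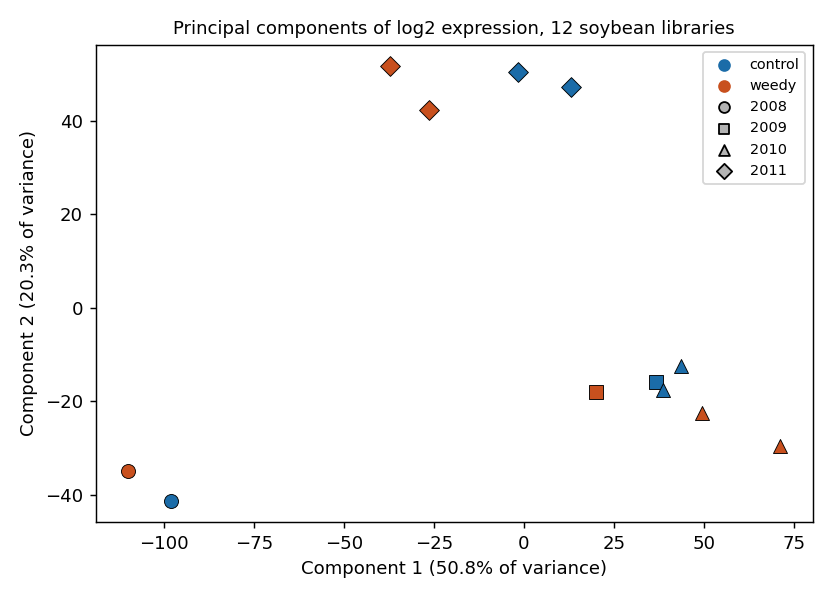
The first (x axis, 50.8% of variance) and second (y axis, 20.3%) principal components of log2 expression, 1 point per library, coloured by group and shaped by season. The 2008 pair lies at -97.8 and -110 on component 1, and the 2011 libraries lie at 42.4 to 51.7 on component 2.

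Leaves from weedy plots held less messenger RNA of some molecular chaperones, the proteins that fold other proteins and are made in larger amounts in heat. Of 183 heat shock proteins and factors measured, 44 fell and 5 rose, adjusted over the list alone, and 134 did not pass. HSP17.6II Glyma14g11420, a small cytosolic heat shock protein, fell by 1.85 ± 0.29 on the log2 scale (SE, n = 6 libraries per group), from 6.24 ± 1.43 (SD) in control to 4.39 ± 1.09 in weedy plots, and 5 of the 6 genes of that name fell. HSP81-1 Glyma16g29750, which encodes a heat-inducible HSP90, fell by 1.77 ± 0.27, and HSFA2 Glyma17g34540, a transcription factor that sustains the heat response, fell by 1.18 ± 0.17. HSFA2 stood at only 1.52 ± 0.56 (SD) in control and 0.35 ± 0.29 in weedy plots, where a value can be a low or floored estimate. All 3 were lower in 6 of 6 pairs of plots, with an adjusted p of 0.00234 over the list alone and 0.101 over all genes (limma). HSP17.6II Glyma14g11420 was chosen after their values were seen.

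The chaperones that fell belonged to several compartments of the cell. The names by which they are grouped here, and mtHSP23.6, were chosen after their values were seen. Among those of the endoplasmic reticulum, where secreted proteins fold, all 3 genes named BIP2, the gene named BIP1, all 3 named ATERDJ3A and both named ATERDJ3B fell, with median log2 differences of -0.73, -0.89, -0.84 and -0.59. Of the chloroplast HSP21 genes 2 of 3 fell (median of these -1.05), of the mitochondrial HSP60 genes 2 of 4 (median of these -0.66), and of the mitochondrial mtHSP23.6 genes 1 of 2, Glyma12g01580, by 1.31 ± 0.21. Among cytosolic HSP70 chaperones 3 of 7 genes named HSP70, 3 of 5 named HSC70-1 and 1 of 4 named HSP70B fell. The median over the 44 fallen genes was -0.70, they ranged from -1.85 to -0.30, and 36 of them were lower in all 6 pairs. These genes were picked by p in the same libraries, so that agreement adds no support. Of all 30456 tested genes 854 were lower and 877 higher in all 6 pairs. The 5 that rose, all named here after their values were seen, were HSP70 Glyma18g52480 (0.58), HSP70B Glyma15g09430 (0.57), the DNAJ protein F7D19.25 Glyma13g36560 (0.52), HSP70 Glyma13g29580 (0.40) and the heat shock factor AHSFA3 Glyma13g21490 (0.36).

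As a set, the heat shock list was lower in weedy plots (camera, adjusted p = 1.5e-11 with the preset correlation, adjusted p = 0.0365 with an estimated correlation, and fry, adjusted p = 0.00285). Its median was -0.10, its mean was -0.26, and its median was below 0 in 6 of 6 pairs. Over all genes 0 members passed, and the list was given the lead after all 18 lists had been seen. With the plot pairs as a block 40 members fell and 3 rose, and the estimated-correlation p was 0.151 (fry, 0.0266), while without the season in the fit 0 members passed and fry gave 0.198. Leaving out any library other than the 2008 pair and control replicate 1 of 2011 raised the estimated-correlation p to between 0.0502 and 0.121, and without the year 2011 16 members fell and 1 rose (estimated-correlation p = 0.135, fry 0.0618). Without the year 2010 the values were 0.284 and 0.0879.

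**Figure D2:**
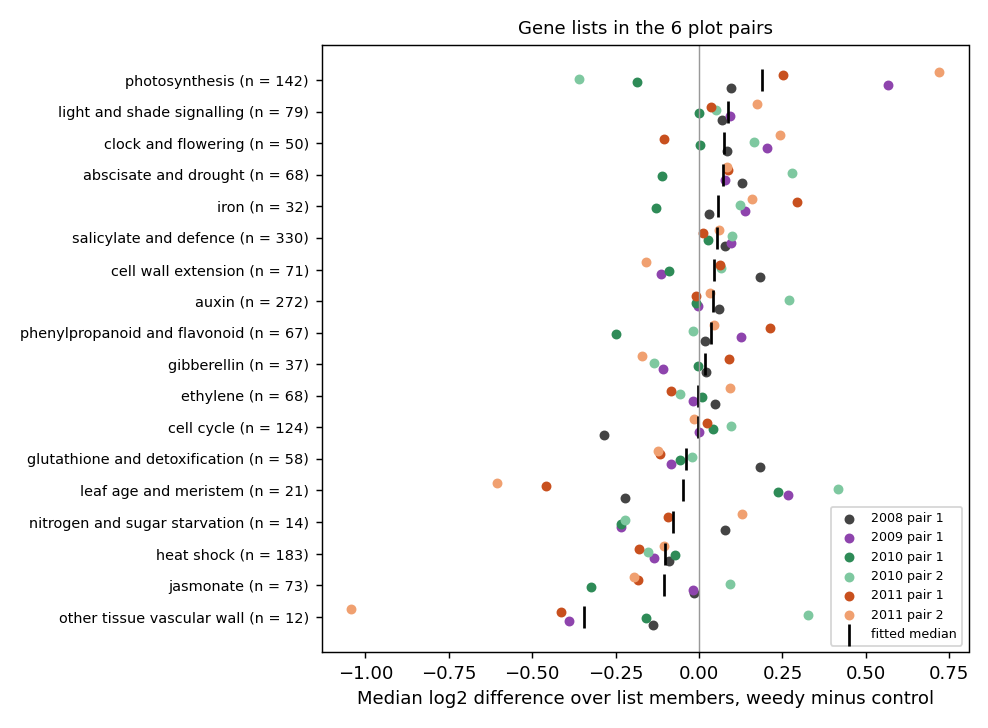
Median log2 difference, weedy minus control, over the members of each of 18 gene lists (y axis, number of members in brackets), 1 coloured point per plot pair and a black bar for the fitted median. The heat shock medians lie below 0 in 6 of 6 pairs, and the photosynthesis medians lie below 0 in the pairs of 2010 (-0.19 and -0.36) and above 0 in the other 4.

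Across all genes, those named here are the 3 of smallest p on each side, and none of them passed. ROF1 Glyma16g10730, a peptidyl-prolyl isomerase of the FKBP class, differed by -0.60 ± 0.07. ASAR1 Glyma17g03520, a small GTPase of secretory vesicles, differed by -0.90 ± 0.12, and CRT3 Glyma11g13460, a calreticulin of the endoplasmic reticulum, by -0.58 ± 0.08. On the other side, the cycling DOF factor CDF3 Glyma04g33410 differed by 0.54 ± 0.07, the 2-oxoglutarate-dependent oxygenase F12K11.24 Glyma15g40890 by 0.57 ± 0.08 and MYC6.16 Glyma09g39230, of unknown function, by 0.40 ± 0.06. Each of these 6 genes differed the same way in 6 of 6 pairs (adjusted p = 0.101 for each), which adds no support, since they were picked by p in the same libraries. In all, 0 of 30456 genes passed the adjusted threshold in limma, while 3293 had an unadjusted p under 0.05, 1652 higher and 1641 lower in weedy plots, against 1523 that chance would give.

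That count moved when single libraries were left out. Leaving out the control library of 2008, the weedy library of 2008 or both gave the same 24 genes, 22 of them lower in weedy plots, and leaving out weedy replicate 1 of 2010 gave 6, all higher and none of them among the 24. These settings of 2008 are in effect the same fit. With the season in the fit, a 2008 library without its partner carries no weedy minus control difference. The 22 included HSP81-1 Glyma16g29750 (-2.02 ± 0.23), the FKBP-type isomerase K15N18.12 Glyma05g28260 (-1.55), the HSP20-like chaperones F22G5.25 Glyma13g24490 (-1.46) and Glyma07g32070 (-1.28), the disaggregase CLPB4 Glyma04g06610 (-0.98), and both NIR1 genes of nitrite reduction, Glyma07g33570 (-1.61) and Glyma02g14910 (-1.53). The 2 higher genes were F12K11.24 Glyma15g40890 (0.64) and the receptor-like kinase K2I5.13 Glyma09g02210 (1.15). Apart from HSP81-1, ASAR1, ROF1, CRT3, NIR1 and F12K11.24, these genes are named after their values were seen.

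Of 50 clock and flowering genes 5 rose in weedy plots, 0 fell and 45 did not pass, adjusted over the list alone: 3 genes named LHY, a Myb-type repressor at the core of the clock, and 2 named AT3G09610, whose Arabidopsis match is the related clock factor RVE8. LHY Glyma19g45030 rose by 0.70 ± 0.13 (adjusted p = 0.0134 over the list alone) and AT3G09610 Glyma03g33440 by 0.57 ± 0.13 (0.0337), in 6 and 5 of 6 pairs. Over all genes neither passed (limma, adjusted p = 0.101 and 0.154). AT3G09610 Glyma03g33440 stood at only 1.25 ± 1.23 (SD) in control and 1.81 ± 1.11 in weedy plots, where a value can be a low or floored estimate. As a set the list was higher with the preset correlation (camera, adjusted p = 4.3e-04, but adjusted p = 0.411 with an estimated correlation and 0.266 by fry). The call of LHY Glyma19g45030 ended without the year 2011 (adjusted p = 0.127) and without the season in the fit (0.973). The list median of 0.07 was 0.12 without weedy replicate 1 of 2010 and 0.13 without weedy replicate 1 of 2011. That of AT3G09610 Glyma03g33440 ended without any 1 library of 2009 or 2011 or control replicate 2 of 2010 (adjusted p between 0.0533 and 0.0984). It also ended without the year 2009 (0.0558), 2010 (0.0524) or 2011 (0.335) and without the season in the fit (0.973). With the plot pairs as a block its adjusted p was 0.0930, which ended the call. LHY Glyma03g42260 (0.75) was chosen after its values were seen and lost its call in 16 of 25 other settings. Among them were the block (0.0930), a minimum mean log2 of 2 (0.0501) and leaving out either library of 2008 (0.0634 and 0.0632) or 2009 (0.0557 and 0.0565), control replicate 2 of 2010 (0.0655) or any library of 2011 (0.0533 to 0.115). It was 0.0626, 0.0558, 0.0524 and 0.127 without the years 2008 to 2011 in turn, and 0.973 without the season in the fit.

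Of 79 genes of light and shade perception 0 passed over the list alone, and 57 lay above 0. Among the bHLH factors named PIF3, which act in phytochrome signalling, values that did not pass lay on both sides: Glyma19g40980 by 0.61 ± 0.13 and Glyma03g38390 by 0.77 ± 0.19, against -0.36 ± 0.09 for Glyma10g28290 and -0.27 ± 0.07 for Glyma20g22280. Their adjusted p over the list alone was 0.0619 for the first 3 and 0.0740 for Glyma20g22280, and Glyma03g38390 and Glyma20g22280 were chosen after their values were seen. Glyma19g40980 passed when control replicate 1 of 2011 (0.0254), weedy replicate 1 of 2010 (0.0115) or weedy replicate 2 of 2010 (0.0470) was left out, and without the year 2010 (0.0483). Glyma03g38390 passed without either library of 2008 (0.0318), both (0.0316) or weedy replicate 1 of 2010 (0.0308), and Glyma10g28290 without either library of 2008 (0.0498 and 0.0497) or both (0.0496). With the leaf stage as a covariate Glyma19g40980 and Glyma10g28290 passed (0.0439 for both). The list median was 0.09 and above 0 in 6 of 6 pairs (camera, adjusted p = 5.6e-04, and adjusted p = 0.306 with an estimated correlation).

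A gibberellin gene of synthesis and another of inactivation rose in weedy plots by the test over their list alone. Over all genes they did not pass (limma, adjusted p = 0.140 for YAP169 Glyma06g16080 and 0.151 for GA2OX8 Glyma05g09920), nor did T26I20.6 Glyma10g40580 (0.142). Of 37 genes 2 rose and 1 fell, adjusted over the list alone: YAP169 Glyma06g16080, a gibberellin 20-oxidase of synthesis, rose by 0.73 ± 0.16, GA2OX8 Glyma05g09920, a 2-oxidase that inactivates the hormone, rose by 1.14 ± 0.26, and the gibberellin-regulated T26I20.6 Glyma10g40580 fell by 0.54 ± 0.12, each with an adjusted p of 0.0148 and the same sign in 6 of 6 pairs. GA2OX8 was chosen after its values were seen, and its call ended without either library of 2009 (0.0564 and 0.0565), without both (0.0562) and without the year 2010 (0.0501). The calls of all 3 ended without the year 2011 (0.112) and without the season in the fit (0.967 for YAP169 and T26I20.6, 0.235 for GA2OX8). In the control plots of 2010 YAP169 stood at only 1.14 and 0.93, where a value can be a low or floored estimate. The list as a whole did not pass (camera, adjusted p = 0.718, median 0.02). Among 58 glutathione transferases, which also act on herbicides, GSTU7 Glyma02g33780 rose by 0.59 ± 0.11 (limma, adjusted p = 0.0155 over the list alone and 0.101 over all genes), 0 fell, and the list median was -0.04 (camera, adjusted p = 0.738). That call ended without either library of replicate 2 of 2011 (0.0514 and 0.0521), without the year 2011 (0.222) and with the plot pairs as a block (0.0536).

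Nitrite reductase messenger was lower in weedy plots except in 2008, by the test over its list alone. Over all genes it did not pass (limma, adjusted p = 0.228 for NIR1 Glyma07g33570 and 0.264 for NIR1 Glyma02g14910). NIR1 Glyma07g33570 fell by 1.22 ± 0.33 and NIR1 Glyma02g14910 by 1.12 ± 0.33, both lower in 5 of 6 pairs, and they were the 2 that fell among 14 genes of nitrate assimilation and starvation, of which 0 rose (adjusted p = 0.0439 over the list alone for both, list median -0.08, camera adjusted p = 0.208). These calls ended when any library outside 2008 was left out (adjusted p between 0.0526 and 0.128), and with the plot pairs as a block (0.0969 for both). With the deposited values read as log2 FPKM and 1 added before the log, the genes differed by -0.98 and -0.94 and neither call held (0.0591 for both). They also ended without the year 2009 (0.127), 2010 (0.238) or 2011 (0.178 and 0.207) and without the season in the fit (0.735). In the 2008 pair both genes were higher in the weedy plot, by 0.78 and 0.95. In the weedy plots of 2010 NIR1 Glyma07g33570 stood at only 0.84 and 1.00, where a value can be a low or floored estimate. The list was lower by camera without the 2008 pair (median -0.091, adjusted p = 0.0237) or either of its libraries (0.0235 and 0.0237), control replicate 2 of 2011 (-0.13, 0.0379) or the year 2011 (-0.14, 0.0143), and with the leaf stage as a covariate (-0.098, 0.0484). It did not pass without any other library, where the median came as close to 0 as -0.017 (without control replicate 2 of 2010), nor without the year 2010, where it was above 0 (0.012, 0.557).

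Another 7 lists were called with the preset correlation, and none of these calls held with an estimated correlation. With the preset correlation, photosynthesis genes (142, median 0.19, adjusted p = 1.9e-09), salicylate and defence genes (330, median 0.05, 4.8e-04), abscisate and drought genes (68, median 0.07, 0.00262), auxin genes (272, median 0.04, 0.00962) and iron genes (32, median 0.06, 0.0258) were higher in weedy plots. Jasmonate genes (73, median -0.10, 0.00312) and secondary wall cellulose synthases, fixed as markers of stem or petiole tissue (12, median -0.34, 0.00962), were lower. The adjusted p with an estimated correlation was 0.606 for photosynthesis, 0.144 for defence, 0.314 for abscisate, 0.411 for iron, and 0.453 for auxin, jasmonate and cellulose synthases. For photosynthesis that correlation was 0.66, against the preset 0.01, so the p with the preset correlation is too small. By fry the defence list passed (adjusted p = 0.0462) and the other 6 did not (0.238 to 0.532). The photosynthesis median was 0.11 without either library of 2009 and 0.12 without control replicate 2 of 2011, and that of cellulose synthases was -0.17 without the latter. The auxin median was 0.074 without either library of 2009 and 0.017 and 0.016 without the control and weedy library of replicate 2 of 2010. The iron median was 0.034 without either library of 2009 and 0.098 without control replicate 1 of 2010, that of jasmonate -0.067 without control replicate 1 of 2010, and that of abscisate 0.11 without weedy replicate 1 of 2010. With the preset correlation the calls of photosynthesis (0.862), iron (0.374), jasmonate (0.103) and cellulose synthases (0.148) ended without the year 2011, and that of auxin without the year 2010 (0.325, median -0.0042). Single libraries ended the calls of auxin (either library of replicate 2 of 2010, 0.209 and 0.101), iron (these 2 libraries, 0.0625 and 0.0545, and both of replicate 1 of 2011, 0.114 and 0.137), jasmonate (both of replicate 1 of 2010, 0.0818 and 0.109) and cellulose synthases (weedy replicate 1 of 2011, 0.0849). Of their members 1 passed over the list alone, MGN6.8 Glyma06g14160 of the abscisate list, which the deposited table places in a family of hydroxyproline-rich glycoproteins. It rose by 0.38 ± 0.08 (0.0458, and 0.139 over all genes by limma). Its call ended when any library but weedy replicate 1 of 2011 was left out (0.0702 to 0.162), when any year was (0.145 to 0.256), with the plot pairs as a block (0.0821), without the season in the fit (0.959), with a pseudocount of 0.1 (0.0517) and with the leaf stage as a covariate (0.0654).

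Another 4 lists gave no call and no member past the test. These were the cell cycle (124 genes, median -0.00, camera adjusted p = 0.760), cell wall extension (71, 0.04, 0.321), phenylpropanoids and flavonoids (67, 0.04, 0.972) and leaf age and meristem genes (21, -0.05, 0.351). The cell cycle list was higher without the 2008 pair (median 0.053, camera adjusted p = 0.0312) or either of its libraries (0.0314 and 0.0315). Leaf age and meristem genes were lower without the year 2009 (median -0.11, 0.0114), either of its libraries (0.0111 and 0.0112), weedy replicate 2 of 2010 (-0.12, 0.0390) or the year 2010 (-0.21, 0.00254), and higher without the year 2011 (0.19, 0.00323). Cell wall extension genes were higher without the year 2009 (0.081, 0.0455) or either of its libraries (0.0457 and 0.0454). With other single libraries left out that list did not pass, and its median ran from -0.028 (without weedy replicate 1 of 2011) to 0.10 (without control replicate 1 of 2010). Phenylpropanoid and flavonoid genes were higher without the year 2010 (0.073, 0.0413). For ethylene (68 genes, adjusted p = 0.760) the median was -0.0031 and the mean 4.3e-05, opposite in sign, and 0 members passed.

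Members with the smallest p of the remaining lists are given as values that did not pass over their list. The SAUR auxin-response genes T3A4.7 Glyma06g13910 and T10D10.10 Glyma07g04850 differed by 0.69 ± 0.16 and -0.58 ± 0.13 (adjusted p = 0.0890 for both), the ethylene-forming enzymes EFE Glyma02g43560 and Glyma17g01330 by 0.91 ± 0.28 (0.268) and 0.48 ± 0.13 (0.221), and the lipoxygenases Os03g0700700 Glyma08g20200 and Glyma13g42330 of the jasmonate list by -1.26 ± 0.36 and -0.51 ± 0.16 (0.161 for both). The Arabidopsis match of both lipoxygenases is LOX1, which is not an enzyme of jasmonate synthesis. The ferric reductase FRO2 Glyma10g37610 differed by 0.47 ± 0.11 (0.0629) and the iron store FER1 Glyma07g19060 by 0.40 ± 0.15 (0.279), MYB111 Glyma03g37640, a regulator of flavonol synthesis, by -0.36 ± 0.08 (0.0588) and T1D16.5 Glyma17g34430, described in the deposited table as of the chalcone-flavanone isomerase family, by -0.26 ± 0.06 (0.0655). The early light-induced proteins ELIP1 Glyma10g38910 and Glyma20g28890 differed by -0.60 ± 0.15 and -0.53 ± 0.15 (0.309 for both), against the direction of the photosynthesis list that holds them. The defence genes MUD21.16 Glyma05g09440 and SAG101 Glyma19g01610 differed by 0.39 ± 0.08 and 0.31 ± 0.07 (0.130 for both), the cyclins CYCD1;1 Glyma08g40150 and CYCB2;3 Glyma11g08960 by 0.33 ± 0.07 (0.0935) and -0.22 ± 0.06 (0.226), and the expansins ATEXLB1 Glyma05g05880 and EXPA1 Glyma01g06030 by 0.25 ± 0.06 and 0.35 ± 0.10 (0.152 for both). The phosphatase HAB1 Glyma09g07650 of abscisate signalling differed by 0.33 ± 0.11 (0.260), the growth-regulating factors AtGRF5 Glyma11g11820 and AtGRF4 Glyma10g07790 by -0.28 ± 0.12 and -0.35 ± 0.16 (0.409 for both), the cellulose synthases IRX1 Glyma08g12400 and CesA9 Glyma04g23530 by -0.85 ± 0.33 and -0.43 ± 0.22 (0.181 for both), and GSTU8 Glyma07g16840 by -0.65 ± 0.20 (0.159). With 1 library left out, FRO2 passed without control replicate 2 of 2011 (0.0423) or weedy replicate 1 of 2010 (0.0209), and with the plot pairs as a block (0.0435), EFE Glyma17g01330 without the former (0.0156), MYB111 and T1D16.5 without the latter (0.0237 and 0.0430), GSTU8 without either library of 2008 (0.0191 and 0.0193) and Os03g0700700 Glyma08g20200 without control replicate 2 of 2010 (0.0461). Without the year 2010 EFE Glyma02g43560 passed (1.42, 0.0113) and so did ELIP1 Glyma10g38910 (-0.33, 0.0483), without 2011 EFE Glyma17g01330 (0.67, 0.0274) and without 2008 GSTU8 (0.0192). MYB111 also passed with the leaf stage as a covariate (0.0422) and by eBayes with neither trend nor robust fitting (0.0425).

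**Figure D3:**
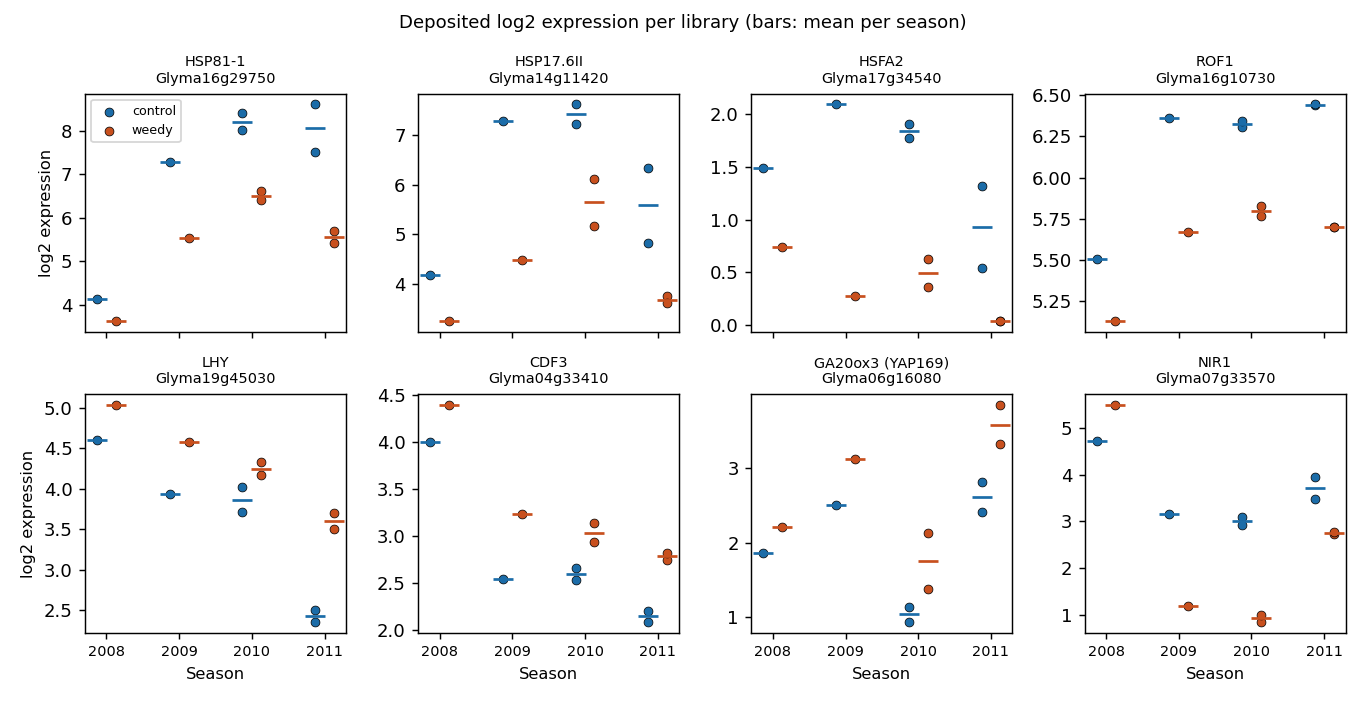
Deposited log2 expression (y axis) by season (x axis) of 8 named genes, 1 point per library, blue for control and orange for weedy, with a bar for the mean of each group in a season. HSP81-1, HSP17.6II, HSFA2 and ROF1 were lower, and LHY, CDF3 and YAP169 higher, in the weedy library of 6 of 6 pairs, while NIR1 was higher in the weedy library in 2008 and lower in the other 5 pairs.

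Within single seasons, tested in 2010 and 2011 where each group had 2 plots, the heat shock list was lower in both. In 2010, with flax, 23 of its members fell and 0 rose, adjusted over the list alone (camera, adjusted p = 4.5e-06, and adjusted p = 0.261 with an estimated correlation), and in 2011, with velvetleaf and sunflower, 31 fell and 0 rose (9.6e-08, and 0.180 with an estimated correlation). In 2010 the NIR1 genes Glyma07g33570 and Glyma02g14910 differed by -2.08 ± 0.17 and -2.02 ± 0.21, the early light-induced protein ELIP1 Glyma10g38910 by -1.14 ± 0.13, and the chitinase T6A9.5 Glyma02g01020, the YABBY factor INO Glyma06g10110 and the auxin response factor ARF4 Glyma12g07560 by 0.99 ± 0.15, 0.78 ± 0.13 and 0.66 ± 0.11. In 2011 the protease inhibitor F2H15.9 Glyma09g29360 differed by -2.79 ± 0.27, the polygalacturonase inhibitor PGIP1 Glyma15g26790 by -2.42 ± 0.26, the lipid-transfer family protein F4L23.31 Glyma05g04490 by -1.39 ± 0.15, carbonic anhydrase CA2 Glyma01g03720 by 1.499 ± 0.18, LHCB4.3 Glyma18g03220 of the light-harvesting antenna by 0.95 ± 0.11 and AT3G09610 Glyma13g19910 by 0.88 ± 0.10. Other lists called within a season with the preset correlation, none of them with an estimated correlation (adjusted p = 0.203 to 0.771), were auxin, cell cycle, clock and leaf age genes higher and jasmonate, nitrogen and phenylpropanoid genes lower in 2010. In 2011 abscisate, clock, iron, light and phenylpropanoid genes were higher, and jasmonate and leaf age genes lower. All these values of 2011 include weedy replicate 2, whose label calls its second read file corrupt.

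None of the single genes named within a season passed over all genes: limma gave 0 of 30456 in 2010 (2632 at an unadjusted p under 0.05, smallest adjusted p = 0.133) and 0 in 2011 (3655, smallest adjusted p = 0.180). Leaving out weedy replicate 1 of 2010 gave 268 genes in 2010, 167 higher and 101 lower. NIR1 Glyma07g33570 was then among them (adjusted p = 0.0246), as were Glyma02g14910 (0.0437), INO (0.0423), ARF4 and ELIP1 (0.0489 for both). That fit leaves 1 weedy plot in 2010, which is assumed to vary like the others.

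The response of photosynthesis genes differed between the 2 seasons with the preset correlation. Light-harvesting, Rubisco small subunit and Rubisco activase genes had a median weedy minus control difference of -0.27 in 2010, where 1 of 142 fell and 0 rose over the list alone (adjusted p = 0.574 with an estimated correlation, fry 0.346). In 2011 the median was 0.47, and 51 rose and 1 fell (adjusted p = 0.284 with an estimated correlation, fry 0.0832). The list median of 2011 was 0.25 in the pair of replicate 1 and 0.72 in that of replicate 2. The label of weedy replicate 2 of 2011 calls its second read file corrupt. Neither the lists within 2011 nor those of the difference between the seasons were retested without that library. In 2011 the markers of stem or petiole tissue had a median of -0.73, and 6 of 12 fell over the list alone (camera, adjusted p = 0.00749, and adjusted p = 0.461 with an estimated correlation). The difference between the seasons, 2011 minus 2010, had a median of 0.74, with 83 genes past the test over the list alone, all upward (camera, adjusted p = 5.0e-39, and adjusted p = 0.289 with an estimated correlation, and fry, 0.0794). The correlation among these genes was estimated at 0.33, against the preset 0.01. The 83 are thus not separate observations, and the p with the preset correlation is too small. Growth-regulating factors and KNOX genes, which mark young leaf and shoot apex, went the other way from photosynthesis genes, with a median of 0.35 in 2010, -0.52 in 2011 and -0.76 for the difference, where 14 of 21 passed downward and 0 upward (1.5e-11, adjusted p = 0.289 with an estimated correlation, fry 0.0283). The heat shock list did not differ between the seasons by this test (median difference -0.04, adjusted p = 0.603).

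Single genes in the same test of the difference were LHCB4.3 Glyma18g03220 (1.29 ± 0.16), the AP2 factor RAP2.7 Glyma02g09600 (1.19 ± 0.16) and AT1G12845 Glyma19g27440 (2.05 ± 0.28) on the upper side, and F4L23.31 Glyma05g04490 (-1.65 ± 0.21), the cyclin CYCD6;1 Glyma06g45510 (-1.03 ± 0.14) and RALFL32 Glyma11g36660 (-1.97 ± 0.29) on the lower. Their adjusted p was 0.279, and 0 of 30456 genes passed in limma (4181 at an unadjusted p under 0.05). Without weedy replicate 1 of 2010, 273 passed, 140 higher and 133 lower, including LHCB4.3 (0.0430), RAP2.7 (0.0488), AT1G12845 (0.0486), F4L23.31 (0.0471) and CYCD6;1 (0.0492).

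The authors' deposited table gives its own test of each of these 2 seasons, and its overlap was compared with the heat shock list alone. Among the 30456 genes, the authors' deposited table lists 750 with q under 0.05 in 2010 (406 higher, 344 lower in weedy plots) and 2336 in 2011 (1368 higher, 968 lower). In the authors' deposited table, 85 genes were lower in both seasons, where independent lists would share 10.9, and 26 of the 85 were on the heat shock list, where 0.511 of its 183 members would be drawn by chance (Fisher's exact test across genes, which are not independent, p = 1.0e-37). The heat shock list had been picked from 18 lists for its fall in data that include these same libraries. This overlap is therefore no independent support for that fall. In the authors' deposited table, 22 genes were higher in both seasons against 18.24 for independent lists, and 0 of them were heat shock genes. Another 208 genes in the authors' deposited table went opposite ways, against 28.4 for independent lists. The 2 seasons share no libraries, and in the deposited ratios 78 of the 85 were also lower in 2009 and 60 in 2008, while 51.9% and 50.3% of all genes were.

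Row spacing, compared in 2010 and 2011 between 18 cm and 76 cm, gave no gene past the test over all genes, and 5 lists called with the preset correlation alone. In the narrow spacing cell cycle (median -0.04, camera adjusted p = 0.0113), cell wall extension (-0.09, 0.0169) and gibberellin genes (-0.08, 0.0169) were lower, and secondary wall cellulose synthases, the markers of stem or petiole tissue (0.36, 0.0145), and glutathione genes (0.08, 0.0362) were higher. With an estimated correlation their adjusted p was 0.246, 0.616, 0.246, 0.616 and 0.395, and 0 of their members passed over the list alone. The seed storage and lipid-transfer family protein AT3G22142 Glyma15g23830 differed by -1.04 ± 0.12, T20D1.90 Glyma05g35670 by -0.97 ± 0.14 and VEP1 Glyma14g09650 by -0.67 ± 0.11 in the narrow spacing, and the kinase MXA21.150 Glyma09g31320, CPuORF10 Glyma08g28440 and T23K23.23 Glyma09g30380 by 0.79 ± 0.13, 0.77 ± 0.14 and 0.63 ± 0.12. Their adjusted p was 0.867 (limma, 0 of 30456 genes, 1716 at an unadjusted p under 0.05). The heat shock list had a median of -0.01 between spacings (adjusted p = 0.553). Whether weeds acted differently at the 2 spacings was tested by the interaction, for which 0 genes passed (625 at an unadjusted p under 0.05). The lowest p among these belonged to AT3G52105 Glyma12g36640 (1.93 ± 0.21), AT1G53903 Glyma16g01550 (1.54 ± 0.19) and AT2G31945 Glyma08g16810 (2.61 ± 0.40) and to F26F24.28 Glyma15g13650 (-1.33 ± 0.22), AT3G44590 Glyma12g30800 (-1.23 ± 0.22) and MIJ24.9 Glyma06g02820 (-0.95 ± 0.19), each with an adjusted p of 1.00. Spacing followed the replicate number, so the 2 cannot be told apart.

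Between seasons most genes changed. COR47 Glyma04g01130, a cold- and drought-induced dehydrin, stood at 0.41 and 0.21 in 2008 and 2009 and at 7.42 and 7.99 in 2010 and 2011. The acid phosphatase VSP1 Glyma08g21390 stood at 1.96 in 2008 and at 9.76, 8.58 and 7.75 afterwards, and the matrixin proteases F23H11.28 Glyma02g03250 and Glyma02g03290 stood at 10.7 and 7.06 in 2009 and 10.3 and 6.71 in 2011 but at 1.06 and 1.31 in 2008 and 1.94 and 2.95 in 2010. The wax synthesis gene CER2 Glyma06g10190, the fatty alcohol oxidase AT3G23410 Glyma12g15940 and the GDSL lipase T4O12.13 Glyma04g02490 stood at 8.31, 8.23 and 8.08 in 2008 and at 2.41, 2.06 and 1.35 in 2011. The small nuclear ribonucleoprotein F17A22.3 Glyma12g18710 stood at 7.34, 8.39 and 0.36 in 2008, 2010 and 2011, and in 2009 at 1.89 in the control and 6.11 in the weedy plot. Each of these 8 passed (adjusted p between 5.2e-09 and 1.4e-04).

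Photosynthesis genes averaged 7.73, 6.89, 6.51 and 7.16 from 2008 to 2011, and leaf age and meristem genes 1.76, 3.28, 3.47 and 2.496. Of 30456 genes 20431 differed between seasons (limma F test), from 531 between 2010 and 2009 to 16910 between 2010 and 2008. Season covers weather, sampling date, weed species, herbicide and any library batch, which cannot be told apart. COR47 is 1 of 12 genes, of 30459, with all libraries of 2010 and 2011 at least 2 log2 units above all of 2008 and 2009. Both matrixin genes are among 7 that part 2008 and 2010 from 2009 and 2011 that widely. For identifiers listed in more than 1 entry, which were left out, the higher entry changed places between 2008 and 2009 on 1 side and 2010 and 2011 on the other in 15 of 18 cases, and between 2008 and 2010 and the other 2 seasons in 2. Whether single-entry genes such as COR47 and the matrixin genes also changed identifier between seasons could not be settled.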

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

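The tests of the photosynthesis pattern, the leaf stage covariate and the count of heat shock members across other settings were chosen only after the results they bear on were seen, as were the splits with the list chosen anew and the rule by which the leaf stage test of photosynthesis is read as open.

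A library stood apart from the other 5 of its group in 33 of 196 groups of 6, 30 for single genes and 3 for list means, and 31 of the 33 were 2008 libraries. If all 6 libraries of a group varied alike, chance would flag about 1 in 20 groups, which would be 9.8. They come from different seasons, and 20431 of 30456 genes differed between seasons (limma F test). A library that is alone in its season, as in 2008, can thus stand apart by season. VSP1, T4O12.13, AT3G23410 and CER2 were even named for their change between seasons. The 33 therefore do not show more stray libraries than chance would give. The number given for each flagged group is the gap to the nearest library as a share of the group's whole range. In control plots the 2008 library was low for ROF1 Glyma16g10730 (0.851), ASAR1 Glyma17g03520 (0.764), CRT3 Glyma11g13460 (0.757), CYCB2;3 Glyma11g08960 (0.755), T26I20.6 Glyma10g40580 (0.816), HSP81-1 Glyma16g29750 (0.702), Os03g0700700 Glyma08g20200 (0.674), PIF3 Glyma19g40980 (0.630), SAG101 Glyma19g01610 (0.897), ARF4 Glyma12g07560 (0.634), CYCD6;1 Glyma06g45510 (0.711) and VSP1 Glyma08g21390 (0.796). It was high for CDF3 Glyma04g33410 (0.703), AT3G09610 Glyma03g33440 (0.667), LHCB4.3 Glyma18g03220 (0.656), CA2 Glyma01g03720 (0.647), RAP2.7 Glyma02g09600 (0.852), T4O12.13 Glyma04g02490 (0.907), AT3G23410 Glyma12g15940 (0.930) and CER2 Glyma06g10190 (0.918). In weedy plots the 2008 library was low for ROF1 (0.781), CRT3 (0.661), CYCB2;3 (0.6996), T26I20.6 (0.808) and SAG101 (0.835), and high for CDF3 (0.705), NIR1 Glyma02g14910 (0.631) and AT3G09610 Glyma13g19910 (0.681). Its list means were also apart and low, for auxin (0.677), cell cycle (0.653) and salicylate and defence genes (0.769). Outside 2008, weedy replicate 2 of 2011 was high for EXPA1 Glyma01g06030 (0.848) and weedy replicate 1 of 2010 was low for GSTU7 Glyma02g33780 (0.660).

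For 4 of 18 lists the weedy minus control difference itself differed between 2011 and 2010 by camera with the preset correlation: photosynthesis (median 0.74, adjusted p = 5.0e-39), leaf age and meristem (-0.76, 1.5e-11), nitrogen and sugar starvation (0.59, 0.00183) and phenylpropanoids and flavonoids (0.18, 0.00483). With an estimated correlation none of the 4 held (adjusted p = 0.289 for the first 3 and 0.735 for the last).

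Any split of the libraries gives at least 0 genes, so the splits say nothing of chance for the count of 0 between weedy and control, which all 100 random splits into 6 and 6 reached. By limma 3293 genes had an unadjusted p under 0.05, a number that 3 of the 32 splits parting all 6 pairs reached, the real one included. The highest other count among these 32 was 4382. At an adjusted p under 0.05, the highest count of another split among the 100 random ones was 446, for a split with the 2008 pair, the 2009 control, both 2011 controls and weedy replicate 2 of 2010 on 1 side, which points to a structure of the samples. The same holds for the count of 0 between row spacings (limma, 1716 at an unadjusted p under 0.05), which all 33 splits that could be fitted reached, with 2 genes as the highest other count.

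The fall of heat shock genes in weedy plots was weighed first. Among 100 random splits of the libraries into 6 and 6, the real one gave 49 heat shock members past the test over the list alone. The highest other count was 43. For this list by itself 1 of 72 splits within seasons, the real one, gave 49 members past the test over the list alone, against 31 for the next, which swapped the 2008 pair. The list was given the lead after all 18 had been seen, and with the leading list chosen anew in each split 3 reached 49, all among the 32 that part all 6 pairs (110 and 74 photosynthesis genes in the others, which swap both pairs of 2010), while 8 of 72 reached its share of members, 26.8%, so whether chance is excluded depends on the splits and the measure and stays open. A different leaf stage in weedy plots was tested with the mean of growth-regulating factor and KNOX genes as a covariate. The median of the 44 fallen members was then -0.686, against -0.695 without it. The list kept its camera call (adjusted p = 8.5e-11), although its adjusted p with an estimated correlation was then 0.0885. These marker genes differed between the groups by a mean of only -0.06, so the covariate could hardly move the median, and the small shift decides nothing. The median of the markers was above 0 in 3 pairs and below 0 in 3, while that of the heat shock list was below 0 in 6 of 6. This argues against leaf stage, as these genes mark it, as the whole cause. Weeds and herbicide differ together between the groups, so a response to either may be a candidate explanation, as a hypothesis that was not tested apart from the other. The label of the 2009 control plot, however, dates its spraying to June 26, after the sampling of June 25. If that date is right, this spraying cannot explain the list median of -0.13 in the 2009 pair. That pair is 1 plot per group and does not settle the other seasons. Nor do the labels give the hour of sampling, so a different hour in weedy plots cannot be told apart from weeds or herbicide.

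The difference of photosynthesis genes between 2010 and 2011 was weighed second. With the leaf stage covariate the median season difference was 0.290, against 0.744 without it, but its median SE rose from 0.265 to 0.960, so leaf stage cannot be told apart from another cause in these 8 libraries. A first reading by the size of the shrinkage alone would have counted for leaf stage, and the SE was brought in after that result. The weed species may also be a cause, as the list median was above 0 in all 4 pairs outside 2010, the season of flax, but species and season changed together and cannot be told apart.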

How the results depend on the processing

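Chosen after the data were seen were the reading of values as log2 FPKM, the higher filter, eBayes without trend, the leaf stage covariate, all changes to the heat shock count, and those to the gene lists other than the estimated correlation, the replicate block and the fit without it. Of 136 recomputed counts 127 stayed within 1.5 times and 9 moved. Of 450 list values 383 kept direction and call, 23 lost and 15 gained a call and 29 changed direction, and of 1471 values of named genes 1323 kept both, 98 lost and 50 gained a call and 0 changed direction. Quantile normalization and no filter test little, since the values already share 1 distribution and the filter removed 3 genes. DESeq2 and size factors were not run, as there are no counts, and what depth limits is unknown.

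Weedy against control gave 0 genes with the replicate block and with neither season nor block (no replicate block), 24 without the year 2008, and 0 to 24 with 1 library left out. With 1 library left out the counts ran from 0 to 268 within 2010 and from 0 to 273 for the difference between seasons. Heat shock members past the test over the list alone numbered 49 with the season in the fit, 43 with the replicate block, 0 with neither season nor block and 17 without the year 2011. Of 10 lists called with the preset correlation 1 held with an estimated correlation. For the heat shock list the adjusted p with an estimated correlation was under 0.05 in 9 of 24 alternatives (0.0205 to 0.284), and that of fry in 21 of 24 (0.00121 to 0.198). The 9 include leaving out either library of 2008 and the year 2008, which are in effect the same fit. The replicate block ended the estimated-correlation call of the heat shock list (0.151) and the calls of 6 named genes and gave 1, FRO2, as printed beside each. It changed no other call of a named gene or, with the preset correlation, of a list. Of the 44 heat shock members that fell, 39 also fell with the block, where 40 fell in all. The cause of these changes was not tested.

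Lists that changed direction in camera had no call in the full data, and the cause was not tested. Their medians were -0.0041 (neither season nor block) and 0.053 (without 2008) for the cell cycle, 0.0012 (without 2008) for ethylene, -0.018 (mean log2 of at least 2) and 0.0011 (without 2011) for glutathione, 0.0042 (leaf stage covariate) and 0.19 (without 2011, camera adjusted p = 0.00323) for leaf age, 0.012 (without 2010) for nitrogen and 0.038 (pseudocount 0.1), 0.013 (leaf stage covariate), 0.011 (without 2009) and -0.064 (without 2011) for phenylpropanoids. With 1 library left out they ran from -0.038 to 0.053 for the cell cycle, which passed without either 2008 library (camera adjusted p = 0.0314 and 0.0315), -0.0050 to 0.033 for ethylene, -0.032 to 0.065 for gibberellin, -0.073 to -0.0066 for glutathione, -0.12 to 0.029 for leaf age, -0.13 to -0.017 for nitrogen and -0.023 to 0.10 for phenylpropanoids.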

Other observations

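The test of morning and evening clock genes was chosen after values of LHY, RVE8, CDF3 and LNK3 genes had been seen, as were the tests without these genes, the comparison of entries with shared identifiers and the stricter reading, by its exact p, of the evening gene test.

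Of 32 soybean genes matched to LHY, RVE8, LNK and CDF factors, which Arabidopsis expresses in the morning, 17 rose and 1 fell in weedy plots by limma, adjusted over these and 22 evening genes, with a median log2 difference of 0.35. This set holds the 6 genes whose rise prompted it, so its count is not independent evidence. Without these 6, 11 of 26 rose and 1 fell, with a median of 0.29, above 0 in 5 of 6 pairs (two-sided exact sign-flip test, p = 0.0625). Without all genes of the 4 factors they belong to, 4 of 16 rose and 1 fell, with a median of 0.09, above 0 in 4 of 6 pairs (exact p = 0.281), so a rise of morning genes as a group was not shown. Among the genes not seen before, CDF3 Glyma17g10920 rose by 0.51 ± 0.10 and CDF2 Glyma02g12080 by 0.50 ± 0.11, while LNK1 Glyma05g24590 fell by 0.61 ± 0.16. The 22 evening genes, of the TOC1, PRR, GI, FKF1 and ELF3 kind, had a median of -0.01 (exact p = 0.906), and TOC1 Glyma04g33110 fell by 0.16 ± 0.05 while PRR5 Glyma07g05530 rose by 0.31 ± 0.10.

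For the morning genes that rose, an earlier hour of sampling in weedy plots is a candidate explanation. It would lower evening genes, and their median was below 0 in 2 of 6 pairs, replicate 1 of 2010 (-0.07) and replicate 1 of 2011 (-0.37). The bound set before the evening genes were seen, a median at or above 0 in at least 4 of 6 pairs, was met and would have counted against an earlier hour. It was too weak, since 4 of 6 pairs lies within chance and evening genes moved both ways (10 higher, 12 lower), so the exact p was required after the result was seen. The hour of sampling, which the labels do not give, therefore cannot be told apart from a response to weeds or herbicide.

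The seasons resembled each other unequally in their response. Across genes, which are not independent, the deposited weedy to control ratios of 2009 and 2011 had a Pearson correlation of 0.35 and those of 2010 and 2011 one of -0.20, while the other 4 pairs of seasons lay between 0.05 and 0.16. Velvetleaf was among the weeds of 2008, 2009 and 2011, and flax was the weed of 2010. The weeds did not order the correlations throughout. The seasons 2008 and 2009, both with velvetleaf and buckwheat, correlated at 0.16, as did 2009 and 2010, which shared no weed. For 2008 with 2011 the value was 0.12, and for 2008 with 2010 it was 0.05.

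Of 18 gene identifiers listed in exactly 2 entries, the higher entry was one in 2008 and 2009 and the other in 2010 and 2011 for 15, and 0 kept the same higher entry in all 4 seasons. For Glyma06g45050 the first entry minus the second was -5.74, -6.52, 6.28 and 7.66 from 2008 to 2011. Among the 30459 genes with 1 entry, 12 had all libraries of 2010 and 2011 at least 2 log2 units above all of 2008 and 2009 and 0 the reverse, against 7 that parted 2008 and 2010 from 2009 and 2011 that widely and 1 that parted 2008 and 2011 from 2009 and 2010.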
